A study of Mus musculus with 25 samples.

How the data were processed

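RNA from the livers of 25 C57BL/6 mice was sequenced by the authors in 2 cohorts, 8 mice aged 20 weeks and 17 mice aged 39 weeks. Per the labels, the authors trimmed reads with Trimmomatic 0.33, aligned them with TopHat2 to GRCm38.p5 and estimated expression with Cufflinks and Cuffnorm, for which no versions are stated. The deposited value of each locus in each mouse is FPKM, scaled between the libraries of a cohort by Cuffnorm with a method that is not stated. The authors' deposited comparison tables hold group values in FPKM, a log2 fold change, a p-value and a q-value per locus, in the format of Cuffdiff, for the 20-week genotypes and for metformin in mice labelled Ncoa5+/- at 39 weeks. Those tables were read as given, with their direction turned so that positive means higher in mice labelled Ncoa5+/- or in treated mice. The cohorts were sequenced at different facilities and on different instruments, so they were analysed apart.

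Some loci are written as 0 for whole groups, and the values per mouse carry no reason for it. A locus at 0 in every mouse of a group, while another group was above 0 in every mouse with a mean of at least 1 FPKM, was treated as a failed estimate and left out, a rule written after the data were seen. This took out 15 loci at 20 weeks and 14 at 39 weeks, of which 11 and 9 are protein coding, among them Ahsg, Apoa2, Ttr and Cyp2e1. Of the loci taken out, 13 and 9 carry the mark for too many fragments in the authors' comparisons, 1 and 3 another mark, and 1 and 2 were not found there by position. Alb is listed at 0 in every mouse and was not analysed here. The files used give no read counts, so read depth is unknown and no counting interval can be given. The spread between mice is the only measure of precision. Gene families with similar sequences and loci that overlap can share reads, and their values are uncertain.

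FPKM was analysed as log2 of FPKM plus a pseudocount of 1, over loci with a mean of at least 1 FPKM in the cohort. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with 2 groups at 20 weeks and 4 groups at 39 weeks, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The comparisons were genotype at 20 weeks, genotype at 39 weeks without and with metformin, metformin in each genotype, treated mice labelled Ncoa5+/- against untreated wild type mice, and the interaction of genotype and metformin. Fold changes are of the label Ncoa5+/- over wild type or of treated over untreated, and ± after a log2 fold change is the standard error. Levels are given as mean FPKM ± SD. Ncoa5 and Cdkn1a were also compared by two-sided exact permutation tests of the mean log2 value, adjusted over the 6 comparisons of groups for each gene. On simulated data with known changes in 100 genes of each size, limma recovered a log2 change of 1 in 64% of genes at 20 weeks and in 81% to 97% in the other comparisons. The changed genes were drawn from loci well above the filter, and a gene list was shifted in the same data. The simulated noise was independent between genes and mice, so any structure among the real samples was absent, and real recovery may be lower. Recovery near the filter, or with few changed genes, was not simulated.

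Gene lists for pathways, cell types and sex-biased liver genes were fixed before the data were examined, and lists with at least 5 tested genes were tested, 37 at 20 weeks and 38 at 39 weeks. Camera with a preset correlation of 0.01 made the calls, and camera with an estimated correlation and fry were run beside it. "Positive" and "negative" count members by the sign of their log2 fold change, whether or not they passed a test. Members that passed "adjusted over the list alone" had their p adjusted within that list, with no correction over lists. For a list called in the same data, such counts are not evidence apart from the call. Genes named in each comparison followed a rule fixed before the data were examined: Ncoa5 and Cdkn1a always; the 10 largest and 10 smallest log2 fold changes among called genes with a regular symbol and no overlap between groups; the 3 members with the smallest p in the direction of each called list; and, where fewer than 5 genes passed, the 5 with the smallest p. The report gives a part of them with values. Of the genes that the rule names, 1 is not reported here. Mdm2, Polk and 2410089E03Rik at 39 weeks, and Bax at 20 weeks, lie outside that rule and were named after their values were seen.

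The alternatives planned before the data were examined were other pseudocounts, other filters, quantile normalization, a median shift of each library, limma without a trend or with array weights, fits of the compared groups alone, and leaving out each mouse in turn. Added after the data were seen were keeping failed estimates at 0, protein-coding genes alone, leaving out libraries whose 50 highest loci take more than 70% of the FPKM sum, leaving out wild type replicates 3 and 4 at 20 weeks, and the list tests under the other scalings. The relation of genotype and metformin effects was compared with 100 simulated draws of unchanged groups and with 10 ways of splitting the shared mice. Replicate numbers follow the order of the samples and pair no mice.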

Results

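Liver RNA was sequenced from 25 C57BL/6 mice, labelled either wild type or Ncoa5+/- (1 targeted copy of Ncoa5, a nuclear receptor coactivator gene). The younger cohort held 8 untreated mice aged 20 weeks, 4 labelled Ncoa5+/- and 4 wild type. The older cohort held 17 mice aged 39 weeks: 4 untreated wild type mice, 5 untreated mice labelled Ncoa5+/-, 3 wild type mice given metformin and 5 mice labelled Ncoa5+/- given metformin. Metformin, a glucose-lowering drug, was given in the drinking water at about 250 mg/kg per day from 8 weeks of age for 31 weeks. Values are FPKM per locus, and the 2 cohorts were sequenced and normalized separately, so no test crosses them. The FPKM sums of the libraries ran from 695645 to 1613500 at 20 weeks and from 857291 to 2089980 at 39 weeks. The files used here hold no read counts, so the depth in reads is unknown. In 3 libraries the 50 highest loci took more than 70% of the FPKM sum: 78.7% in wild type replicate 4 at 20 weeks, 78.3% in untreated Ncoa5+/- replicate 3 and 72.5% in metformin-treated Ncoa5+/- replicate 5 at 39 weeks. Of 46499 and 46052 loci, 10963 at 20 weeks and 11441 at 39 weeks had a mean FPKM of at least 1 and were tested.

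Ncoa5, the targeted gene (chromosome 2, GRCm38.p5, 165000275 to 165034867 in the older cohort), did not separate the labels. At 20 weeks its level was 3.88, 2.90, 5.03 and 3.61 FPKM in the 4 mice labelled Ncoa5+/- and 3.56, 3.11, 5.30 and 4.08 FPKM in the 4 wild type mice. At 39 weeks the 5 untreated mice labelled Ncoa5+/- had 4.42, 3.58, 2.63, 3.67 and 4.31 FPKM of Ncoa5, against 4.28, 4.68, 4.12 and 3.60 FPKM in the 4 untreated wild type mice. Under metformin, Ncoa5 stood at 3.32, 3.87, 3.88, 3.07 and 3.63 FPKM in the mice labelled Ncoa5+/- and at 3.68, 3.58 and 6.64 FPKM in wild type mice. Ncoa5 means were 3.85 ± 0.88 against 4.01 ± 0.94 FPKM at 20 weeks (SD, n = 4 and 4; two-sided exact permutation p = 0.8, adjusted 0.8). They were 3.72 ± 0.71 against 4.17 ± 0.45 FPKM in untreated mice at 39 weeks (n = 5 and 4; exact permutation p = 0.333, adjusted 0.667). Under metformin the Ncoa5 means were 3.55 ± 0.35 against 4.63 ± 1.74 FPKM (n = 5 and 3; exact permutation p = 0.196, adjusted 0.589). Treated mice labelled Ncoa5+/- against untreated wild type mice gave an exact permutation p of 0.0794 for Ncoa5 (adjusted 0.476), and an unadjusted 0.0357 without untreated wild type replicate 4. Groups are therefore named by their labels, and every genotype direction rests on those labels; the labels do not describe the deleted part, so the locus value cannot place a single mouse.

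Cdkn1a, which encodes the cell cycle inhibitor p21 named in the series title (chromosome 17, 29090979 to 29100722), was far higher in older mice labelled Ncoa5+/-. Untreated at 39 weeks it reached 40.3 ± 43.6 FPKM (SD, n = 5) against 1.81 ± 0.61 FPKM in wild type mice (n = 4), a ratio of means of 22.3. All 5 mice labelled Ncoa5+/- lay above all 4 wild type mice: 117, 17.7, 15, 18.3 and 33.5 FPKM against 1.28 to 2.68 FPKM (exact permutation p = 0.00794, the smallest possible; 0.0238 adjusted over the 6 group comparisons). Under metformin Cdkn1a stood at 18.2 ± 6.5 FPKM in mice labelled Ncoa5+/- (n = 5) and 0.804 ± 0.218 FPKM in wild type mice (n = 3; exact permutation p = 0.0179, the smallest possible, adjusted 0.0357). At 20 weeks the means were 5.16 ± 4.78 and 0.667 ± 0.277 FPKM (n = 4 and 4), but the mice labelled Ncoa5+/- ran from 0.666 to 10.4 FPKM and the difference did not pass the test (exact permutation p = 0.0571, adjusted 0.0686). It reached an unadjusted exact permutation p of 0.0286 without Ncoa5+/- replicate 2.

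**Figure D1:**
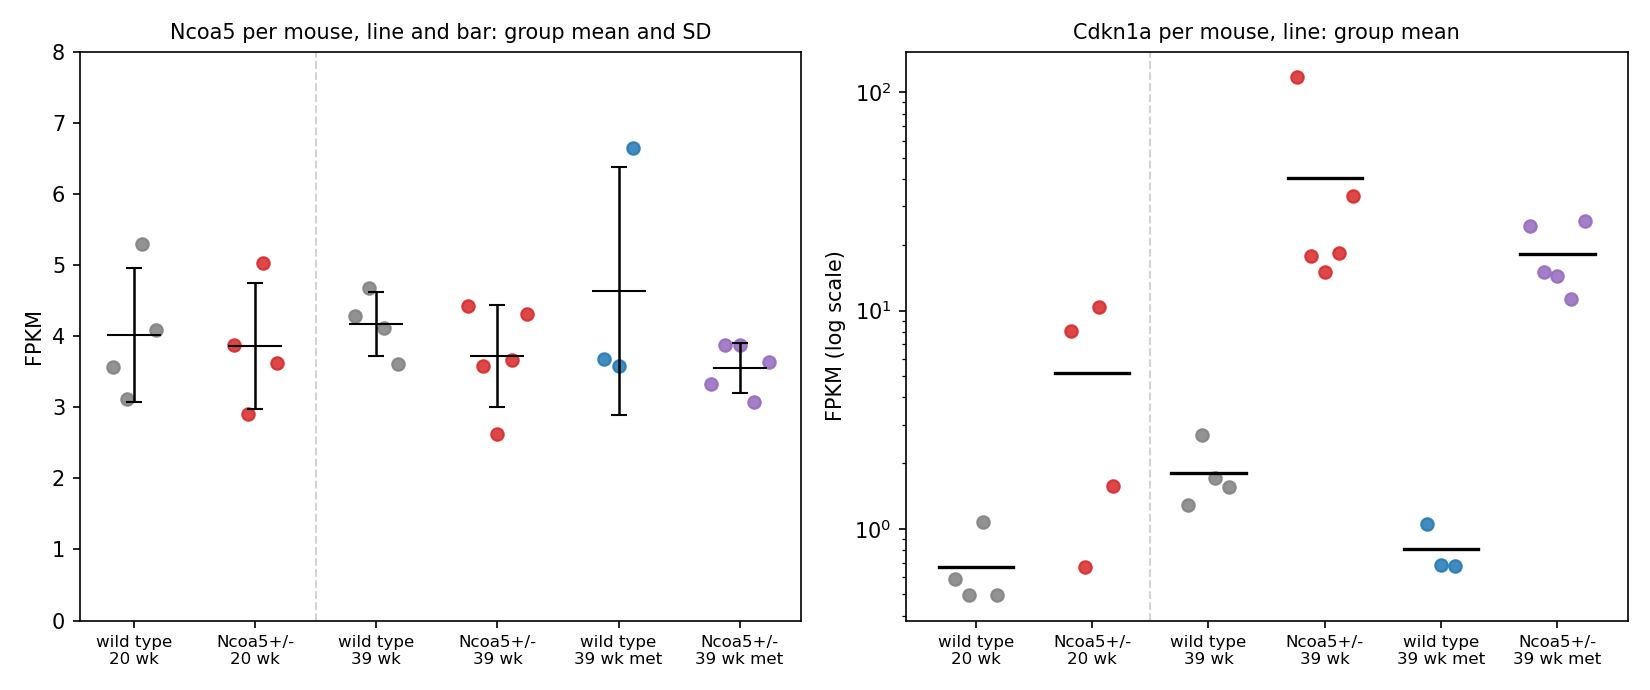
Ncoa5 (left, linear axis) and Cdkn1a (right, log axis) in FPKM in every mouse, by group, with "met" for metformin; points are mice, the line is the group mean and the left panel's bar the SD. Ncoa5 overlaps between the labels in all 3 pairs of groups, while Cdkn1a in the older mice labelled Ncoa5+/- lies at 11.3 FPKM or more and in wild type mice at 2.68 FPKM or less.

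Metformin was compared with no treatment in mice labelled Ncoa5+/-, since the series title asks whether the drug reverses a liver state with p21-expressing hepatocytes. Mean Cdkn1a was lower with the drug, at a ratio of 0.450, yet 3 of the 5 untreated values lay inside the treated range of 11.3 to 25.7 FPKM, and the test was not passed (log2 difference -0.70; exact permutation p = 0.302). Without untreated Ncoa5+/- replicate 1, which held 117 FPKM, the log2 difference in Cdkn1a shrank to -0.21. In wild type mice Cdkn1a was 0.804 ± 0.218 FPKM with metformin and 1.81 ± 0.61 FPKM without (n = 3 and 4), with no overlap of the values and an exact permutation p of 0.0571 (adjusted 0.0686). The unadjusted p became 0.0286, the smallest possible, with a pseudocount of 0.1 in place of 1.

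At 20 weeks the genotype comparison asks whether livers labelled Ncoa5+/- already differ from wild type livers in younger mice. Endoplasmic reticulum chaperone genes, which fold and export proteins, lay higher in mice labelled Ncoa5+/-: 21 of 21 measured members were positive, with a median log2 fold change of 0.55. With camera's estimated correlation neither this list nor any other of the 37 was called (smallest adjusted p = 0.591). Creld2 stood at 52.4 ± 18.8 against 17.6 ± 7.4 FPKM (SD, n = 4 and 4; log2 fold change 1.54 ± 0.34 SE), Hyou1 at 54.5 ± 9.4 against 30.1 ± 8.7 FPKM and Syvn1, a ubiquitin ligase of that organelle, at 37.4 ± 4.8 against 21.4 ± 6.8 FPKM. Acute phase genes, secreted by hepatocytes in inflammation, were positive in 24 of 24, among them Orm1 at 1467 ± 337 against 925 ± 179 FPKM. Cholesterol synthesis genes were negative in 21 of 22, with Lss at 8.79 ± 3.16 against 23.4 ± 14 FPKM. Fatty acid synthesis genes were negative in 16 of 18, with Acacb at 8.58 ± 1.6 against 11.9 ± 1.2 FPKM. No gene passed limma's test over all genes (0 of 10963; smallest adjusted p = 0.603), while 820 lay under an unadjusted p of 0.05, 554 higher and 266 lower. In 64% of 100 simulated genes, all well above the filter, a log2 change of 1 was recovered at this size, in data that gave 168 calls. The simulated mice had independent noise without the structure among the real samples described below, so real recovery may be lower. Recovery near the filter, or with few changed genes, was not simulated.

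Other lists called at 20 weeks, by camera with a preset correlation alone, held genes of p53, of stress responses and of other cell types. Of 16 measured p53 target genes 13 were positive, among them Trp53inp1 at 22.8 ± 6.9 against 10.8 ± 2.0 FPKM and Btg2, an antiproliferative gene, at 8.10 ± 4.66 against 2.39 ± 0.39 FPKM (n = 4 and 4). ATF4 and integrated stress response genes were positive in 14 of 16, with Gdf15, a stress-induced hormone, at 3.23 ± 2.08 against 1.06 ± 0.40 FPKM, and proteasome subunit genes in 24 of 30, with Psma1 at 84.4 ± 3.8 against 69.6 ± 7.3 FPKM. Macrophage and Kupffer cell markers were negative in 14 of 14, with Clec4f, a Kupffer cell lectin, at 15 ± 2.2 against 22.2 ± 5.5 FPKM, and Vsig4 at 4.41 ± 1.38 against 8.51 ± 3.46 FPKM. Endothelial markers (13 of 16) and stellate cell markers (8 of 9) were mostly negative too, while all 5 erythroid markers were positive. Igfbp1, a fasting-induced gene, stood at 55.1 ± 55.0 against 6.60 ± 4.65 FPKM. Adjusted over the list alone, 13 chaperone genes, 2 p53 target genes, 1 periportal gene (Etnppl) and 1 fasting-response gene (Igfbp1) passed, against 0 over all genes. These lists were called in the same data, so the counts are not evidence apart from the list calls.

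Camera with a preset correlation called 17 of 37 lists at 20 weeks, 11 higher and 6 lower. The calls that stayed without any single mouse were chaperones (adjusted p = 3.06e-11), acute phase (1.69e-08), macrophage (1.69e-08), cholesterol synthesis (1.24e-07), p53 targets (0.00148), fatty acid synthesis (0.0026), ATF4 (0.00862) and proteasome (0.00907). With an estimated correlation none was called, the smallest adjusted p being 0.591, and quantile normalization called 13 lists, 7 higher and 6 lower. The endothelial (camera adjusted p = 0.00329), NRF2 and glutathione, periportal and pericentral (0.0114 each), immediate early (0.016), stellate and erythroid (0.0169 each), complex I (0.0292) and fasting-response (0.0445) calls were each lost without at least 1 mouse. The endothelial and erythroid calls were lost without wild type replicate 2 (adjusted p = 0.0602 and 0.0706) and the NRF2 call without Ncoa5+/- replicate 1 (0.0746). Stellate (up to 0.109) needed wild type replicates 2 and 4 and Ncoa5+/- replicate 4, and fasting-response (up to 0.423) wild type replicates 2 and 4 and Ncoa5+/- replicate 1. Complex I (up to 0.537) needed wild type replicates 3 and 4 and Ncoa5+/- replicates 2 and 4. Periportal (up to 0.121) and pericentral (up to 0.247) needed wild type replicate 2 and Ncoa5+/- replicate 3, and immediate early (up to 0.277) wild type replicate 1 and Ncoa5+/- replicate 4. Without wild type replicates 3 and 4, which resembled each other more than the rest, cholesterol synthesis and proteasome were no longer called (adjusted p = 0.146 each), complex I turned downward (0.00301), 10 of the 17 lists stayed called and 5 genes passed limma's test. Without wild type replicate 4 alone, 4 genes passed. With the labels of Ncoa5+/- replicate 1 and wild type replicate 2 exchanged, 1115 genes passed.

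At 39 weeks the untreated genotypes differed in 30 of 11441 genes by limma, 29 higher and 1 lower in mice labelled Ncoa5+/-. Of the 30, 8 are predicted or unnamed loci. The largest log2 fold change and the smallest adjusted p belonged to 2410089E03Rik, a locus with a clone name (4.27, adjusted p = 0.000106). Beside Cdkn1a (log2 fold change 3.43 ± 0.45 SE, adjusted p = 0.0017), the p53 target Phlda3, a repressor of Akt, rose from 0.933 ± 0.313 to 17.1 ± 15.9 FPKM (SD, n = 4 and 5; log2 fold change 2.92 ± 0.39, adjusted p = 0.0017). Bax, which promotes apoptosis, rose from 37.0 ± 2.6 to 70 ± 7.7 FPKM (0.90 ± 0.11, adjusted p = 0.000768), and the p53-induced receptor gene Eda2r from 0.327 ± 0.086 to 2.91 ± 1.88 FPKM (1.46 ± 0.22, adjusted p = 0.00536). Plk2 rose from 3.91 ± 0.78 to 10.6 ± 2.1 FPKM (adjusted p = 0.00536), and Ccnd1, the gene of cyclin D1, from 7.81 ± 0.75 to 21 ± 4.5 FPKM (adjusted p = 0.00655). Mbl2, a secreted lectin of innate immunity, rose from 312 ± 26 to 794 ± 217 FPKM (adjusted p = 0.00237). These 7 genes passed without any single mouse, with adjusted p at most 0.0375, but Eda2r did not pass with a pseudocount of 5 (log2 fold change 0.54, adjusted p = 0.0821). All 30 genes had groups without overlap, a property that 1.81% of all tested genes had and chance gives 1.59%.

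Other calls at 39 weeks were less stable. Gsta1, a glutathione transferase gene, stood at 69.1 ± 19.4 against 22.7 ± 8.7 FPKM (adjusted p = 0.0117), but was lost without wild type replicate 2 or 4 (adjusted p up to 0.0689). Atp8b5, a flippase gene, stood at 3.45 ± 2.73 against 0.229 ± 0.132 FPKM (0.0128) and was lost without wild type replicate 2, 3 or 4 (up to 0.0639). The only lower gene, the cation transporter gene Slc22a3, at 0.657 ± 0.109 against 1.75 ± 0.43 FPKM (0.0333), kept its call without 3 of 9 mice, as did Ccng1, a p53 target (25.8 ± 12.0 against 10.6 ± 0.6 FPKM; 0.0464). Gstm1 (0.0361) and Gstm3 (0.0363) kept theirs without 1 of 9 mice; adjusted p rose to at most 0.142 for Slc22a3, 0.186 for Ccng1, 0.162 for Gstm1 and 0.172 for Gstm3. Gsta1, Gstm1 and Gstm3 belong to families of similar sequence whose reads could have been shared, so their values are uncertain. The count fell to 18 without wild type replicate 2 or wild type replicate 4. Fitted without the treated groups, 11 genes passed, and Cdkn1a (adjusted p = 0.0764), Phlda3 (0.0762) and Eda2r (0.151) did not.

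Among gene groups at 39 weeks, p53 target genes rose in mice labelled Ncoa5+/-: 17 of 20 measured members were positive, 7 passed over all genes and 10 adjusted over the list alone. The 3 that passed over the list alone but not over all genes were Aen, Mdm2, whose product degrades p53, and Polk, a DNA polymerase gene. NRF2 and glutathione genes, which detoxify reactive molecules, rose as well, with 19 of 22 positive, 3 past the threshold over all genes and 5 adjusted over the list alone. Both calls stayed without any single mouse (camera adjusted p = 1.12e-17 and 8.62e-10). They held with an estimated correlation (camera adjusted p = 0.045 for each). The glutathione transferase genes called over all genes, Gsta1, Gstm1 and Gstm3, have the uncertain values described above. Of these, Gstm1 and Gstm3 each kept their call without 1 of 9 mice. Cytosolic ribosomal protein genes were positive in 44 of 48 (median log2 fold change 0.10; camera adjusted p = 4.74e-08), with Rps19 at 477 ± 50 against 374 ± 26 FPKM. Mitochondrially encoded genes were negative in 6 of 7 (0.00209), with mt-Cytb, the cytochrome b gene, at 4959 ± 1558 against 8562 ± 826 FPKM and past the threshold adjusted over the list alone, and NF-kB and inflammatory cytokine genes in 15 of 17 (0.0077), with Ccl2 at 1.02 ± 0.52 against 3.06 ± 3.31 FPKM. With an estimated correlation these 3 were not called (adjusted p = 0.603, 0.492 and 0.492).

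Fetal liver and liver tumour genes were positive in 9 of 11 at 39 weeks, with Afp, the fetal albumin-like gene used as a tumour marker, at 1.64 ± 0.68 against 0.968 ± 0.248 FPKM. Immediate early genes were negative in 16 of 16, with Fos at 0.716 ± 0.297 against 21.3 ± 37.0 FPKM, and chaperone genes in 17 of 21, with Hspa5, the main chaperone of the endoplasmic reticulum, at 304 ± 214 against 568 ± 469 FPKM. These 3 calls (camera adjusted p = 0.00969 each) gave adjusted p = 0.492, 0.666 and 0.738 with an estimated correlation. The fetal liver call was lost without wild type replicate 2 or 4 (adjusted p up to 0.0654) and the immediate early call without wild type replicate 2 or Ncoa5+/- replicate 5 (up to 0.499). The chaperone call was lost without wild type replicate 2 or 4 or Ncoa5+/- replicate 1 or 2 (up to 0.824). Senescence-associated genes as a list were not called (6 of 11 positive, adjusted p = 0.11), nor were cell cycle genes (9 of 13 positive, 0.0762) or extracellular matrix and fibrosis genes (11 of 18 positive, 0.0649). Camera called 8 of 38 lists, and 13 to 16 lists without wild type replicate 1, 2 or 3 or Ncoa5+/- replicate 3 or 4.

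**Figure D2:**
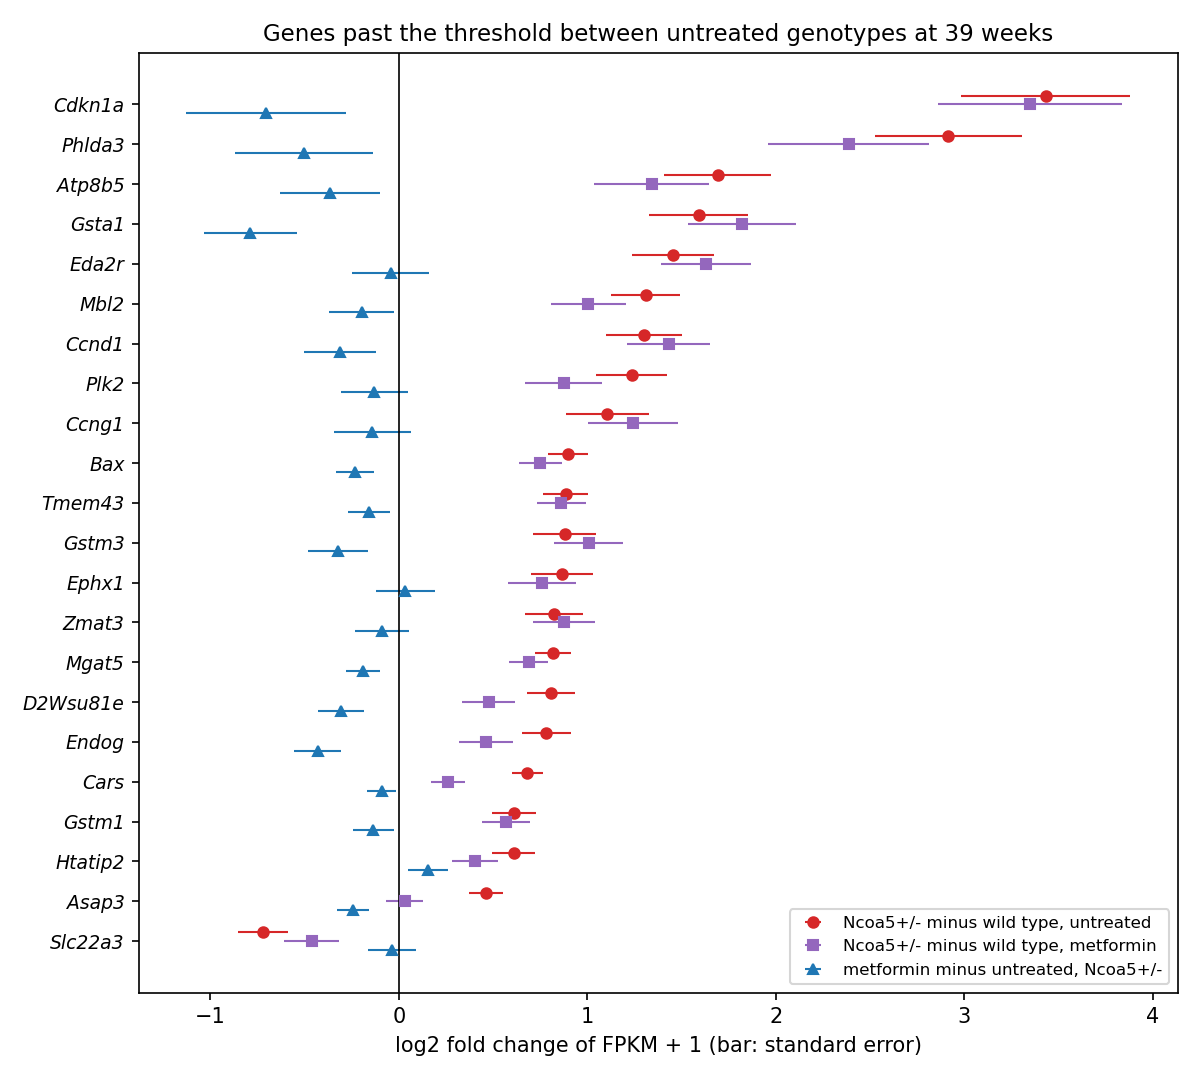
Log2 fold change of FPKM + 1 with its standard error (horizontal axis) for the genes past the threshold between untreated genotypes at 39 weeks, the 8 predicted or unnamed loci left out. Circles compare untreated genotypes, squares the genotypes under metformin and triangles metformin against no treatment in mice labelled Ncoa5+/-; Cdkn1a stands at 3.43, 3.35 and -0.70. Endog and D2Wsu81e share a locus, so their values are uncertain.

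Under metformin the comparison of genotypes asks whether the difference between labels persists in treated mice. By limma 18 of 11441 genes were higher in treated mice labelled Ncoa5+/- than in treated wild type mice, and 0 were lower. Among the 18 genes, Cdkn1a had the largest log2 fold change of those with a regular symbol (3.35 ± 0.49 SE, n = 5 and 3, adjusted p = 0.00886). The locus 2410089E03Rik, which has a clone name, stood at 3.62 (adjusted p = 0.00138). Eda2r stood at 2.56 ± 0.51 against 0.142 ± 0.036 FPKM (SD, adjusted p = 0.00886). Bax stood at 59.7 ± 8.2 against 35.0 ± 5.0 FPKM (0.00975) and Ccnd1 at 17.2 ± 5.8 against 5.49 ± 0.72 FPKM (0.00975). Tmem43, a nuclear membrane protein gene, stood at 8.02 ± 0.75 against 3.97 ± 0.68 FPKM (0.00917), Gsta1 at 39.6 ± 11.3 against 10.6 ± 4.0 FPKM (0.0105), and Aen, a p53-induced nuclease gene, at 19.7 ± 4.2 against 7.78 ± 1.79 FPKM (0.0325). Phlda3 (0.0325), Gstm3 (0.0354) and the stress kinase gene Zak (0.0389) passed too. All 18 had groups without overlap, against 3.72% of all tested genes and 3.57% by chance.

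With 3 treated wild type mice, these calls leaned on each of them. The count fell from 18 to 11, 4 and 5 without treated wild type replicate 1, 2 and 3. Cdkn1a, Eda2r, Bax and Gsta1 were lost without treated wild type replicate 2 or 3 (adjusted p up to 0.0743, 0.0743, 0.104 and 0.125), Tmem43 without replicate 1 or 2 and Ccnd1 without any of the 3 (up to 0.0905 each). Aen, Phlda3 and Gstm3 kept their call without 1 of 8 mice and Zak without 0 of 8 (adjusted p up to 0.241, 0.243, 0.248 and 0.295). With any single mouse left out, the log2 fold change of Cdkn1a stayed between 3.21 and 3.49. With a pseudocount of 5, 10 genes passed and Cdkn1a did not (log2 fold change 1.95, adjusted p = 0.174); with the treated groups fitted alone, 6 passed.

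Among treated mice, p53 target genes were higher as a group in mice labelled Ncoa5+/- than in wild type mice, with 16 of 20 positive, 5 past the threshold over all genes and 10 adjusted over the list alone. NRF2 and glutathione genes were higher too, with 21 of 22 positive, 2 over all genes and 5 adjusted over the list alone. Both calls stayed without any single mouse (camera adjusted p = 1.01e-18 and 8.44e-16) and with an estimated correlation (adjusted p = 0.0278 and 0.0131). The glutathione transferase genes called over all genes here, Gsta1 and Gstm3, belong to families of similar sequence, so their values are uncertain. Of the 16 lists camera called, 4 more stayed without any single mouse: ribosomal protein genes, negative in 45 of 48 (2.52e-09), PPAR-alpha and fatty acid oxidation genes, positive in 23 of 25 (1.19e-05), female-biased liver genes, positive in 7 of 7 (0.000607), and cell cycle genes, positive in 11 of 13 (0.000837). Those 4 gave adjusted p = 0.555, 0.5, 0.239 and 0.182 with an estimated correlation. Among their members were Rplp1 at 1468 ± 178 against 1802 ± 147 FPKM, Ehhadh, an enzyme of peroxisomal fatty acid oxidation, at 128 ± 22 against 94.2 ± 20.8 FPKM, Cyp2a4 at 14.2 ± 13.5 against 0.277 ± 0.179 FPKM and Cdk1 at 2.12 ± 0.67 against 1.19 ± 0.25 FPKM. None of these 4 genes passed over all genes; adjusted over the list alone, Cyp2a4 passed.

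The other 10 lists called under metformin each lost their call without at least 1 mouse. Senescence-associated genes were positive in 8 of 11 (camera adjusted p = 0.0261; adjusted p = 0.239 with an estimated correlation), with Cdkn1a alone past the threshold, and the call was lost without treated wild type replicate 3 or treated Ncoa5+/- replicate 1 (up to 0.378). Acute phase genes (18 of 20 negative, 0.00228) needed treated wild type replicate 3 (0.257 without it), and cholesterol synthesis genes (21 of 22 negative, 0.00342) treated wild type replicate 2 (0.617 without it). Male-biased liver genes (12 of 13 negative, 0.00855) needed treated wild type replicates 2 and 3 and treated Ncoa5+/- replicate 4 (up to 0.204), and bile acid genes (15 of 19 negative, 0.0246) treated wild type replicates 2 and 3 (up to 0.38). Mitochondrially encoded genes (6 of 7 negative, 0.0196) needed treated wild type replicate 2 and treated Ncoa5+/- replicate 1 (up to 0.358). Complex I subunit genes (26 of 34 negative, 0.0282) and other respiratory chain genes (29 of 37 negative, 0.0196) needed treated wild type replicates 1 and 2 and treated Ncoa5+/- replicates 1 and 2 (up to 0.651 and 0.906). Ribosome biogenesis genes (20 of 22 positive, 0.0338) needed treated wild type replicates 1 and 2 and treated Ncoa5+/- replicates 2 and 3 (up to 0.914). Pericentral hepatocyte genes (8 of 15 negative, 0.0282), with Glul at 316 ± 33 against 464 ± 12 FPKM, kept their call without 3 of 8 mice (up to 0.299). With an estimated correlation these 10 were not called, the adjusted p running from 0.182 for bile acid genes to 0.784 for both respiratory chain lists. Without treated wild type replicate 2, camera called 9 lists in place of 16. Of the 16 lists 7 were higher and 9 lower, while quantile normalization gave 14, with 10 higher and 4 lower, and kept 11 of the 16.

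Treated mice labelled Ncoa5+/- against untreated wild type mice shows how far treated livers stood from untreated controls. Of 11441 genes 30 passed limma's test, 25 higher and 5 lower. Bax at 59.7 ± 8.2 against 37.0 ± 2.6 FPKM (SD, n = 5 and 4; adjusted p = 0.0108), Eda2r at 2.56 ± 0.51 against 0.327 ± 0.086 FPKM (0.00939) and Htatip2, an oxidoreductase gene, at 61.0 ± 5.1 against 35.5 ± 2.9 FPKM (0.00748) were higher, as was Rec8, a meiotic cohesin gene, at 4.65 ± 1.07 against 1.40 ± 0.18 FPKM (0.00939). Gpt2, a mitochondrial alanine aminotransferase gene, fell from 191 ± 23 to 123 ± 12 FPKM (0.0102). These 5 genes passed without any single mouse. Cdkn1a stood 10.1 times higher than in untreated wild type mice (log2 fold change 2.73 ± 0.45 SE, adjusted p = 0.0115), and missed the threshold without wild type replicate 3 or 4 (up to 0.057). Phlda3 (0.0113) missed it without wild type replicate 3 (0.0585), Tmem43 (0.0114) without wild type replicate 2 or 4 (up to 0.0537), and Mbl2 (0.0114) and Plk2 (0.0137) without wild type replicate 2, 3 or 4 (up to 0.056 and 0.0687). The nucleoside transporter gene Slc29a1 fell from 164 ± 12 to 102 ± 19 FPKM (0.0108), and missed it without wild type replicate 2 or 3 (up to 0.0546).

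Prodh, a proline catabolism gene, Slc22a3 and Dexi were lower in treated mice labelled Ncoa5+/- than in untreated wild type mice (adjusted p = 0.0194, 0.02 and 0.0445), and Ephx1, an epoxide hydrolase gene, and Cbr3, a carbonyl reductase gene, higher (0.0287 and 0.0336). Prodh and Slc22a3 kept their call without 4 of 9 mice and Dexi, Ephx1 and Cbr3 without 2 of 9 (adjusted p up to 0.087, 0.0914, 0.144, 0.126 and 0.126). The count moved to 19, 15 and 16 without wild type replicate 2, 3 and 4, and to 76 without treated Ncoa5+/- replicate 4. The lower genes were 16 of 45 called with array weights and 1 of 27 with the 2 groups fitted alone, which kept 16 of the 30. With failed estimates kept at 0, which adds loci at 0 in a whole group, they were 16 of 44. All 30 genes had groups without overlap, against 4.48% of all tested genes and 1.59% by chance. With a pseudocount of 5, Cdkn1a did not pass (adjusted p = 0.101). Camera called 13 of 38 lists here, and with an estimated correlation none (smallest adjusted p = 0.177). The 7 calls that stayed without any single mouse were p53 targets (16 of 20 positive, 5 genes over all genes and 10 adjusted over the list alone; 9.13e-11), NRF2 and glutathione (19 of 22 positive, 0 and 7; 6.12e-07), ribosomal protein (44 of 48 positive; 1.11e-06), PPAR-alpha (21 of 25 positive, 0 and 1; 6.53e-05), chaperones (20 of 21 negative; 3.12e-05), fasting response (17 of 20 negative, 1 and 3; 0.000379) and NF-kB (15 of 17 negative, 0 and 5; 0.000592). Acute phase genes (17 of 20 negative, 0.00255) needed wild type replicate 4 (0.238 without it) and immediate early genes (14 of 16 negative, 0.00567) wild type replicate 2 (0.881 without it). Interferon-stimulated (22 of 24 negative, 0.0139), stellate (10 of 14 positive, 0.0383), other respiratory chain (27 of 37 positive, 0.0415) and male-biased genes (11 of 13 positive, 0.0415) kept their calls without 5, 6, 3 and 4 of 9 mice (up to 0.339, 0.31, 0.241 and 0.353).

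Metformin against no treatment in mice labelled Ncoa5+/- moved no single gene past limma's test (0 of 11441; smallest adjusted p = 0.166), while 1010 lay under an unadjusted p of 0.05, 452 higher and 558 lower. PPAR-alpha and fatty acid oxidation genes lay higher with the drug, positive in 24 of 25 with a median log2 fold change of 0.20. With camera's estimated correlation neither this list nor any other of the 38 was called (smallest adjusted p = 0.415). Hadhb, of the mitochondrial trifunctional protein, stood at 99.8 ± 8.8 against 80.4 ± 3.7 FPKM (SD, n = 5 and 5). Periportal hepatocyte genes were negative in 16 of 17, with Sds, a serine-degrading enzyme gene, at 91.7 ± 36.0 against 177 ± 96 FPKM and Gls2 at 205 ± 57 against 322 ± 87 FPKM. Androgen-dependent and male-biased genes were positive in 11 of 13, with Elovl3 at 87.4 ± 26.9 against 49.4 ± 19.2 FPKM. Bile acid synthesis and transport genes were positive in 13 of 19, with Cyp27a1 at 324 ± 37 against 270 ± 18 FPKM. Evi5, with the smallest p of all, stood at 32.6 ± 2.8 against 23.8 ± 1.9 FPKM and did not pass. The p53 target genes were negative in 16 of 20, with a median log2 fold change of -0.09, and were not called (camera adjusted p = 0.273), nor were NRF2 and glutathione genes (0.883).

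In this comparison camera called 13 of 38 lists, and with an estimated correlation none (smallest adjusted p = 0.415). PPAR-alpha (camera adjusted p = 4.93e-10), periportal (0.000321), male-biased (0.00125) and bile acid genes (0.0164) stayed called without any single mouse; adjusted p = 0.468, 0.684, 0.684 and 0.415 with an estimated correlation. Adjusted over the list alone, 2 PPAR-alpha, 3 periportal, 1 male-biased, 2 stellate and 1 fasting-response gene passed, against 0 over all genes. Lipid droplet genes were positive in 16 of 20 (0.0141), with Plin2 at 403 ± 139 against 262 ± 45 FPKM and Cidec at 18.6 ± 10.3 against 7.11 ± 3.68 FPKM, a call lost without untreated Ncoa5+/- replicate 5 (0.0654). Macrophage markers, positive in 14 of 15 (0.0164), needed untreated replicate 2 (0.573 without it), and stellate markers, positive in 10 of 14 (0.0141), untreated replicate 2 and treated replicate 1 (up to 0.129). Endothelial markers, positive in 12 of 16 (0.0397), needed untreated replicate 2 and treated replicates 1 and 5 (up to 0.983). Interferon-stimulated genes, negative in 21 of 24 (0.0153), needed untreated replicate 1 and treated replicates 1 and 2 (up to 0.588). Fasting-response genes, negative in 15 of 20 (0.0164), needed untreated replicate 2 and treated replicates 2 and 5 (up to 0.0829). Acute phase (18 of 20 negative, 0.0361), chaperone (15 of 21 negative, 0.0361) and other respiratory chain genes (27 of 37 positive, 0.0196) kept their calls without 5, 6 and 4 of 10 mice (up to 0.194, 0.873 and 0.343). Without treated replicate 5, camera called 8 lists.

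In wild type mice metformin likewise moved no single gene past limma's test (0 of 11441; smallest adjusted p = 0.155), with 1070 under an unadjusted p of 0.05, and 1 gene passed without treated replicate 1. Cytosolic ribosomal protein genes lay higher with the drug: 44 of 48 were positive, with a median log2 fold change of 0.22. Adjusted over the list alone 17 passed, which is not evidence apart from the call of the list. With camera's estimated correlation no list was called in this comparison (smallest adjusted p = 0.283). Against the same 4 untreated wild type mice, the list's median was also 0.10 in untreated and 0.11 in treated mice labelled Ncoa5+/-, so these results are not independent. Rpl38 stood at 1778 ± 361 against 1112 ± 73 FPKM (SD, n = 3 and 4) and Rpl26 at 655 ± 92 against 450 ± 15 FPKM. Genes of the respiratory chain lay higher too, complex I in 26 of 34, with Ndufs4 at 80.6 ± 7.3 against 63.6 ± 4.3 FPKM, and the other complexes in 27 of 37, with Uqcrh at 488 ± 57 against 377 ± 20 FPKM. Male-biased genes were positive in 12 of 13, with C6, a complement gene, at 126 ± 18 against 75.6 ± 13.4 FPKM. Glycolysis and insulin-induced genes were negative in 16 of 17, with Pgam1 at 86.1 ± 7.1 against 106 ± 6 FPKM, and NF-kB and inflammatory cytokine genes in 15 of 17, with Cxcl10, an interferon-induced chemokine, at 1.96 ± 0.80 against 5.16 ± 1.21 FPKM. Adjusted over the list alone, 7 other respiratory chain, 2 NF-kB, 3 fasting-response and 1 glycolysis gene passed.

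Camera called 12 of 38 lists in this comparison, and with an estimated correlation none (smallest adjusted p = 0.283). The ribosomal protein (camera adjusted p = 1.07e-19), male-biased (6.48e-05), other respiratory chain (0.000231), complex I (0.00027), NF-kB (0.00377) and glycolysis calls (0.00505) stayed without any single mouse; adjusted p = 0.517, 0.517, 0.801, 0.801, 0.517 and 0.343 with an estimated correlation. Chaperone genes (20 of 21 negative, 0.000254), with Hspa5 at 232 ± 100 against 568 ± 469 FPKM, and immediate early genes (16 of 16 negative, 0.000254), with Fos at 0.455 ± 0.148 against 21.3 ± 37.0 FPKM, lost their calls without untreated wild type replicate 2 (0.0957 and 0.287). Bile acid genes (15 of 19 positive, 0.00795) needed treated replicate 2 (0.124 without it). Fasting-response genes (16 of 20 negative, 0.0199), with Slc37a4, the glucose-6-phosphate transporter gene, at 96.4 ± 10.7 against 139 ± 21 FPKM, needed untreated and treated replicate 2 (up to 0.287). Female-biased genes (7 of 7 negative, 0.0373), with Cyp2b9 at 0.408 ± 0.390 against 11.1 ± 5.3 FPKM, needed untreated replicate 1 and treated replicate 3 (up to 0.264). Interferon-stimulated genes (20 of 24 negative, 0.0133) needed untreated replicates 1 and 4 and treated replicate 1 (up to 0.288).

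**Figure D3:**
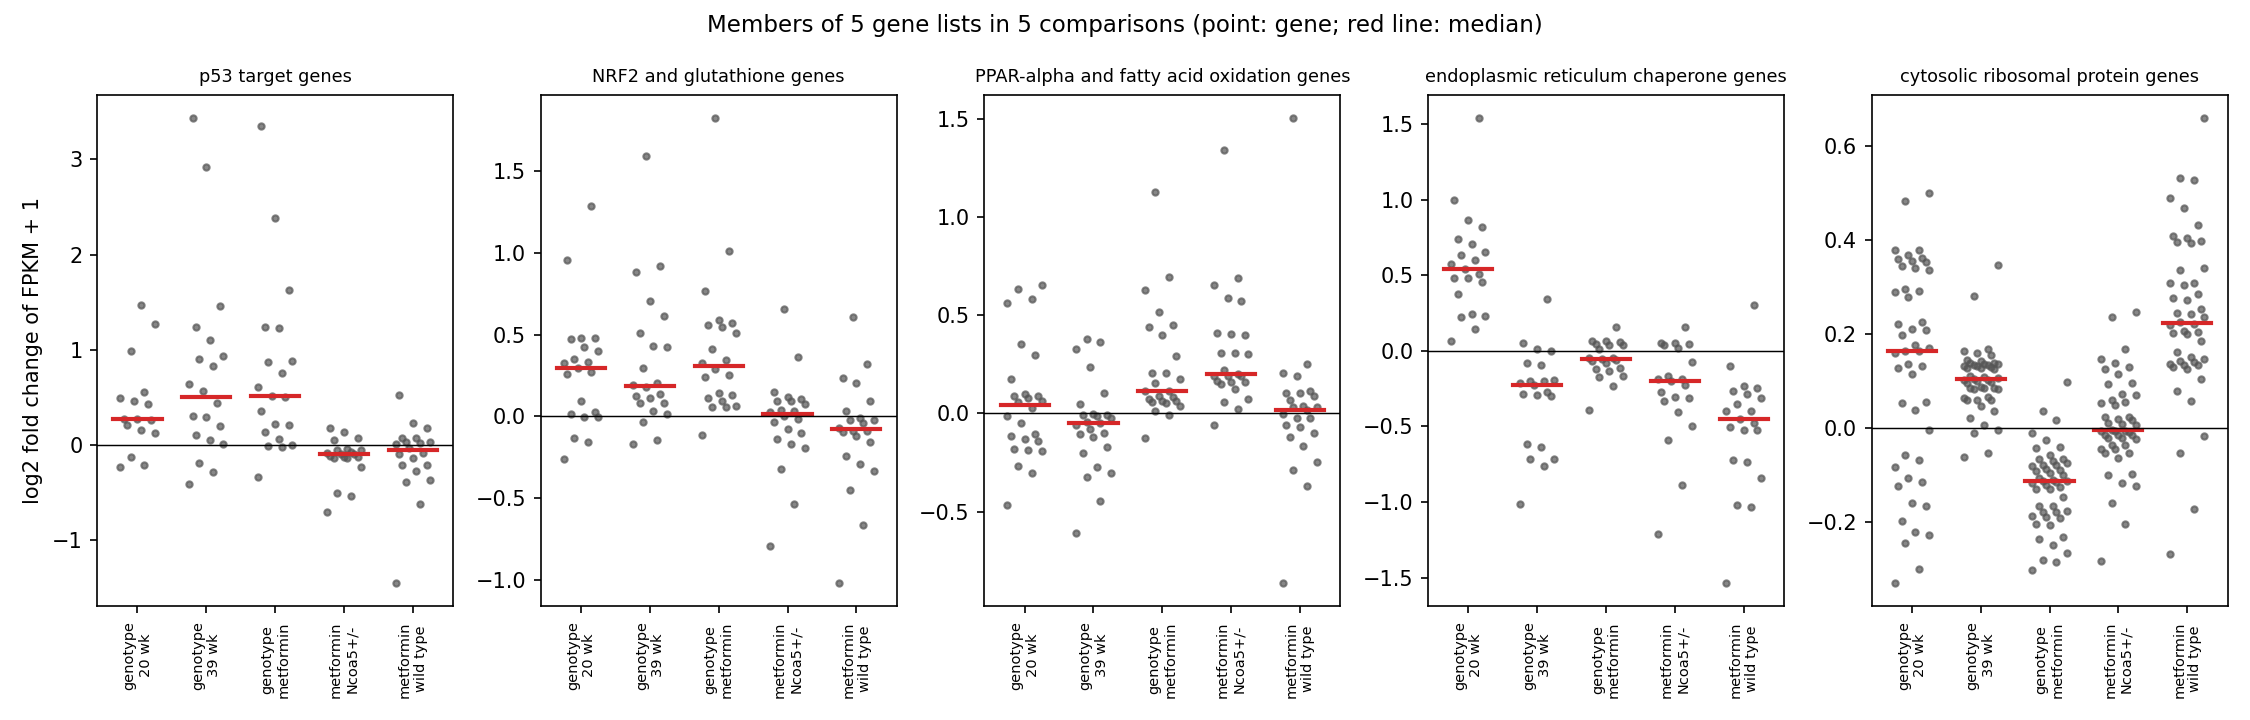
Log2 fold change of FPKM + 1 (vertical axis, its scale differs between panels) of every tested member of 5 gene lists in 5 comparisons; points are genes and red lines medians. The median of p53 target genes is 0.50 and 0.51 between genotypes at 39 weeks, untreated and under metformin, and -0.09 and -0.06 for metformin in mice labelled Ncoa5+/- and in wild type mice.

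The interaction asks whether metformin acted differently in the labelled genotypes. No gene passed limma's test (0 of 11441; smallest adjusted p = 0.991), with 319 under an unadjusted p of 0.05, and 1 gene passed without treated wild type replicate 1. For Cdkn1a the interaction was -0.08 ± 0.66 (log2, SE). Ribosomal protein genes were negative in 47 of 48 (median -0.23), the drug's log2 change in mice labelled Ncoa5+/- being smaller than in wild type mice, and PPAR-alpha and fatty acid oxidation genes positive in 24 of 25 (median 0.20), with Plin2 at an interaction of 0.82 ± 0.32. Both calls stayed without any single mouse (camera adjusted p = 3.2e-19 and 3.66e-06), but with an estimated correlation adjusted p = 0.824 for each, and none of the 8 called lists was called. Camera called 4 lists without treated wild type replicate 2 and 5 without treated Ncoa5+/- replicate 2. A log2 interaction of 1 was recovered in 81% of 100 simulated genes, all well above the filter and in data with many changed genes.

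The effects of genotype and of metformin were set against each other across genes at 39 weeks, to see whether the drug moved genes back. Of the 30 genes past the threshold between untreated genotypes, 25 had the opposite sign under metformin in mice labelled Ncoa5+/- (median -0.18, signed by the genotype effect), and none of the 30 passed the test for metformin. Both comparisons share the 5 untreated mice labelled Ncoa5+/-, which can by itself give opposite signs. In 100 simulated draws of unchanged groups, 88.7% of the top 30 genes were opposite on average, against 83.3% here, and 79 draws were as high. The draws held no genotype effect, so their top genes were picked on noise in the shared mice. For genes with a real difference the share could be lower. The draws therefore cannot decide whether sharing accounts for the 25 genes. Across all 11441 genes, which are not independent replicates, Pearson's r was -0.33 and the covariance -0.03, against simulated means of -0.47 and -0.04; r was as low in 90 of 100 draws. With the shared mice split between both comparisons in 10 ways, r lay between 0.03 and 0.15 in all 20 values, and the covariance averaged 0.01. In treated mice all 30 genes kept the sign of the untreated genotype effect against treated wild type mice, at a median of 1.01 beside 1.17, and 15 passed the test there. The 30 were picked by the untreated comparison, and such a choice can raise the 1.17. The lower values in treated mice therefore do not show an effect of the drug. Independent lists would share 0.047 calls, but these lists are not independent, as the same fit gave both a shared spread. With the compared groups fitted alone, 11 genes passed between untreated genotypes and 6 under metformin.

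The 20-week and 39-week genotype effects come from different mice and runs, so age and run cannot be told apart. The 20-week fold changes are uncertain, since exchanging the labels of Ncoa5+/- replicate 1 and wild type replicate 2 gave 1115 called genes against 0 as labelled. Across 10002 genes in both cohorts, Pearson's r was 0.03 and Spearman's rho 0.08, and 51.2% had the same sign. It turned negative without 20-week wild type replicate 3 (-0.01), or 39-week wild type replicate 1 (-0.04), wild type replicate 4 (-0.01) or Ncoa5+/- replicate 2 (-0.04). Of the genes called at 39 weeks, 21 were measured at 20 weeks and 19 had the same sign there, with a median log2 fold change of 0.44, though none passed at 20 weeks. Bax stood at a log2 fold change of 0.50 at 20 weeks and Gsta1 at 1.29, beside 0.90 and 1.59 at 39 weeks. At an unadjusted p under 0.05, 52 genes were shared where 39.0 are expected, 46 of them with the same sign.

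The authors' deposited comparison tables, in the format of Cuffdiff, counted more differences than limma did. At 20 weeks 294 genes were marked significant by the authors, 180 higher and 114 lower in mice labelled Ncoa5+/-; of the 222 tested by limma, 222 had the same sign and 105 an unadjusted p under 0.05. For metformin in mice labelled Ncoa5+/- the authors marked 173 genes, 54 higher and 119 lower with the drug, and of the 112 tested by limma 111 had the same sign and 46 an unadjusted p under 0.05. In those tables Cdkn1a stood at 5.15 against 0.679 FPKM at 20 weeks (authors' q-value 0.00413) and at 20.1 with metformin against 43.5 FPKM without (authors' q-value 0.00668), while Ncoa5 was not marked in either (authors' q-values 0.998 and 0.9997). Creld2 was marked in both tables, 52.2 against 17.1 FPKM at 20 weeks and 20.7 with metformin against 50.3 FPKM without. Phlda3 was marked for metformin, at 11.8 against 19.5 FPKM, where limma gave an adjusted p of 0.708.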

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

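The test of the 39-week genes in the 20-week cohort, the test without wild type replicates 3 and 4, the list tests under other scalings, the choice of the 3 patterns weighed and the choice of the lists whose own splits are given were made after the results were seen.

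Between untreated genotypes at 39 weeks, 30 genes passed, among them the p53 target genes Cdkn1a, Bax and Phlda3. Of 100 splits of the 9 mice into groups of the same sizes, 1 gave as many (30 in the real split, at most 6 in the others), which makes chance unlikely but does not exclude it. A single library or a single wrong label as the whole cause is argued against by at least 18 of the called genes staying called whichever mouse was left out, the scaling of the libraries by at least 29 staying called under each of the other scalings, and DNA of another strain around the targeted locus by 0 of the 30 lying within 20 Mb of Ncoa5, where 2.20% of all tested genes lie. In the 20-week cohort 90.5% of the 21 genes measured had the same sign, but 12 of the 70 assignments of those mice to groups of 4 gave as many (19 in the real one, at most 21 in the others), while 1 of 70 gave as high a median; r over all genes was 0.03 and p53 target genes gave as small a camera p in 3 of 35 splits, so an effect of the label at both ages stays open. Unequal cages or litters stay open too, since the labels give none.

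Ribosomal protein genes lay higher with metformin in wild type mice. Untreated and treated mice labelled Ncoa5+/- stood above the same untreated wild type mice too (median log2 fold change 0.10 and 0.11). For metformin in mice labelled Ncoa5+/- the median was -0.005. These comparisons share mice, so the drug's effect cannot be told apart here from a low level in the untreated wild type mice. Of 35 splits of the 7 mice, 1 gave as small a camera p for this list (2.82e-21, the smallest other 6.82e-18), which does not exclude chance, as the list was chosen out of 38 after the results were seen. These genes are short (median transcript 809 bases against 2072 for all genes), but among 10000 lists matched on transcript length the list's median stood at percentile 100, which argues against length bias as the whole cause. Scaling is argued against by a camera adjusted p of 4.61e-15 under quantile normalization. A median shift moves a list and all other genes alike, so it hardly tests scaling here. The genes vary together, and the call was lost with an estimated correlation (adjusted p = 0.517). A difference in RNA quality or in the time of feeding or sampling was not tested and stays open beside an effect of the drug, with 3 treated mice.

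At 20 weeks camera with a preset correlation called 17 gene lists between the labels while 0 genes passed limma's test (820 at an unadjusted p under 0.05), and with an estimated correlation and with fry 0 of the 37 lists were called (smallest adjusted p = 0.591 and 0.186). Of 35 splits, 5 gave as many lists (17 in the real split, at most 20 in the others), so chance could not be excluded; endoplasmic reticulum chaperone genes alone gave as small a camera p in 1 of 35 (8.27e-13, the smallest other 1.07e-10). With 0 genes all 35 splits gave as many, which says nothing about chance, but 1115 genes in the split that exchanged Ncoa5+/- replicate 1 and wild type replicate 2 point to a structure of the samples, whose source was not tested, and an exchange of these 2 labels stays open beside it. Without wild type replicates 3 and 4, 10 of the 17 lists stayed called, so whether these libraries give the pattern cannot be told apart from a difference between the labels, as their removal also leaves 2 wild type mice. Scaling as the whole cause is argued against by 12 of the 17 lists staying called under quantile normalization. A median shift moves a list and all other genes alike, so it hardly tests scaling for list calls. Macrophage markers stood below and erythroid markers above the wild type level, so the mix of cells or blood in the samples may have differed, which was not tested.

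Dixon's rule, which picks about 1 in 20 groups of values by chance, picked 8 of 91. Untreated Ncoa5+/- replicate 3 at 39 weeks had an FPKM sum of 2089980 (991881 to 1119810 in the other 4 mice) and a share of 78.3% in its 50 highest loci (54.9% to 58.0%). Untreated Ncoa5+/- replicate 4 had 19416 loci above 0 (20187 to 20435 in the others). Untreated Ncoa5+/- replicate 1 had 6.24 FPKM of Eda2r (1.62 to 2.36) and 8.99 FPKM of Zak (5.01 to 5.35), and untreated Ncoa5+/- replicate 5 had 44.5 FPKM of Htatip2 (54.7 to 59.1). Treated Ncoa5+/- replicate 1 had 103 FPKM of Gpt2 (124 to 134) and treated Ncoa5+/- replicate 4 had 88.3 FPKM of Prodh (66.2 to 71.7).

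For the interaction of genotype and metformin, 8 lists were called (camera adjusted p with a preset correlation). The interaction was positive for PPAR-alpha and fatty acid oxidation genes (3.66e-06), immediate early genes (0.00492), glycolysis and insulin-induced genes (0.0116), lipid droplet genes (0.0203) and ribosome biogenesis and MYC target genes (0.0408). It was negative for ribosomal protein genes (3.2e-19), complex I subunit genes (0.025) and periportal hepatocyte genes (0.0408). With an estimated correlation none of the 8 was called (smallest adjusted p = 0.73), and 68 of 100 splits called as many lists (8 in the real split, at most 17 in the others), so chance could not be excluded for their number; alone, ribosomal protein genes gave as small a camera p in 2 of 100 splits (8.43e-21, the smallest other 4.98e-24), glycolysis genes in 3 (0.00122, the smallest other 9.74e-06) and PPAR-alpha genes in 5 (1.93e-07, the smallest other 1.36e-13), out of 38 lists.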

How the results depend on the processing

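Keeping failed estimates at 0, protein-coding genes alone, leaving out libraries dominated by a few loci, leaving out wild type replicates 3 and 4 at 20 weeks and the list tests under other scalings were chosen after the results were seen. Of 3605 values of named genes under alternatives other than leaving out a mouse, 3524 kept direction and side of the threshold, 72 lost their call, 4 gained a call and 5 turned; of 2864 values without a mouse, 2732, 119, 3 and 10. With failed estimates kept at 0, genes called became 13 for genotype at 20 weeks (from 0), 4 and 2 for metformin in mice labelled Ncoa5+/- and in wild type mice (from 0), 31 for genotype under metformin (from 18) and 5 for the interaction (from 0), with 8 lower genes (from 1) between untreated genotypes at 39 weeks. That setting added 14 loci at 20 weeks and 11 at 39 weeks, each at 0 in every mouse of a group. A call at such a locus can come from the missing estimate alone. Without dominated libraries, 4 genes were called at 20 weeks and 13 lists (from 8) for genotype at 39 weeks; without wild type replicates 3 and 4, 5 genes were called at 20 weeks and Ndufb7 (-0.00560), Ndufv2 (-0.0365) and Ncoa5 (0.15) turned. With the compared groups fitted alone, 11 genes (from 30) were called between genotypes at 39 weeks and 6 (from 18) under metformin; with a pseudocount of 5, 10 under metformin. Without a filter, 2 genes were called for metformin in wild type mice and 2 for the interaction. With a pseudocount of 0.1, Cdkn1a for metformin in wild type mice was -1.05 (exact permutation p = 0.0286) and its interaction turned to 0.33; with array weights Ncoa5 for metformin in mice labelled Ncoa5+/- turned to 0.00208. With camera's estimated correlation and with fry, lists called were 0 and 0 at 20 weeks, 2 and 2 between genotypes at 39 weeks, 0 and 0 for metformin in each genotype, 2 and 2 under metformin, 0 and 2 for treated mice labelled Ncoa5+/- against untreated wild type mice, and 0 and 0 for the interaction, which had 5 lists under quantile normalization. Except where stated, the cause was not tested. Leaving out each mouse in turn gave these lowest and highest values. Genes called: 0 to 4 for genotype at 20 weeks, 18 to 27 at 39 weeks, 0 to 0 and 0 to 1 for metformin in mice labelled Ncoa5+/- and in wild type mice, 4 to 19 for genotype under metformin, 15 to 76 for treated mice labelled Ncoa5+/- against untreated wild type mice and 0 to 1 for the interaction. Lists called, in that order: 12 to 18, 6 to 16, 8 to 16, 11 to 14, 9 to 16, 9 to 17 and 4 to 12. Log2 difference in Ncoa5, in that order: -0.16 to 0.070, -0.20 to -0.05, -0.13 to 0.0125, -0.16 to 0.21, -0.40 to -0.03 and -0.24 to -0.14, and -0.25 to 0.12 for the interaction; in Cdkn1a, 1.04 to 1.96, 2.94 to 3.66, -0.93 to -0.21, -0.72 to -0.48, 3.21 to 3.49 and 2.59 to 2.87, and -0.31 to 0.41 for the interaction. The relation of genotype and metformin effects ran from -0.42 to -0.27 and that of the ages from -0.0418 to 0.15. No sex term was run, since no cohort showed both sexes by the planned genes, as the locus name of Xist was not found and all mice had signal of Y-linked genes. No paired analysis was possible because replicate numbers only follow the order of the samples. FPKM without counts limits what can be said of genes near 1 FPKM.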

Other observations

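The tests of single lists over the splits were chosen after the results were seen.

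Beyond the genes above, Mgat5, a glycosyltransferase gene, was higher in untreated mice labelled Ncoa5+/- at 39 weeks (log2 fold change 0.82, limma adjusted p = 0.00076) and under metformin (0.69, adjusted p = 0.00917), a gene chosen after its values were seen. At 20 weeks mt-Tl1, a mitochondrial leucine tRNA gene, stood at 1151 ± 316 FPKM in mice labelled Ncoa5+/- and 256 ± 197 FPKM in wild type mice (SD, n = 4 and 4; limma adjusted p = 0.603), the smallest p of the named genes there. With metformin in wild type mice, Rps21 stood at 1580 ± 164 against 1024 ± 83 FPKM and Snrpe, a spliceosome gene, at 95.8 ± 5.7 against 75.7 ± 1.0 FPKM (n = 3 and 4), and neither passed.

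The other splits of the mice bear on the remaining results. For genes called under metformin between genotypes, 1 of 56 splits gave as many (18 in the real split, at most 1 in the others). For treated mice labelled Ncoa5+/- against untreated wild type mice, 2 of 100 did (30 in the real split, at most 36 in the others). The 36 came from the split that put treated Ncoa5+/- replicate 4 with the 4 wild type mice and parted the other 8 as labelled. These ranks make chance unlikely for both counts but do not exclude it. Without treated Ncoa5+/- replicate 4, 76 genes passed. The 36 and the 76 point to a structure among the treated mice labelled Ncoa5+/-, whose source was not tested. With 0 genes in the real split every split gives as many, which says nothing about chance: 100 of 100 for metformin in mice labelled Ncoa5+/- (at most 3 in the others), 35 of 35 for metformin in wild type mice (at most 72) and 100 of 100 for the interaction (at most 36). The 72 and 36 genes point to a structure of the samples, whose source was not tested. For the number of lists called, as many came from 92 of 100 splits between untreated genotypes at 39 weeks (8; at most 24), 46 of 100 for metformin in mice labelled Ncoa5+/- (13; at most 21) and 9 of 35 for metformin in wild type mice (12; at most 16). The count was 3 of 56 between genotypes under metformin (16; at most 20) and 31 of 100 for treated mice labelled Ncoa5+/- against untreated wild type mice (13; at most 16), so chance could not be excluded for any of these 5 counts.

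For single lists, p53 target genes gave as small a camera p in 1 of 100 splits between untreated genotypes at 39 weeks (2.96e-19, the smallest other 1.03e-18) and in 1 of 56 under metformin (2.66e-20, the smallest other 1.33e-12). NRF2 and glutathione genes did so in 2 of 100 (4.54e-11, the smallest other 3.98e-11) and in 1 of 56 (4.44e-17, the smallest other 4.80e-10), and as these 2 lists were chosen out of 38 after the results were seen, the counts do not exclude chance. At 20 weeks p53 target genes gave as small a p in 3 of 35 splits (2.00e-04, the smallest other 1.16e-07), and for metformin in mice labelled Ncoa5+/- PPAR-alpha and fatty acid oxidation genes in 5 of 100 (1.30e-11, the smallest other 2.51e-16), so chance could not be excluded for these.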
